A study of Homo sapiens with 33 samples.

How the data were processed

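Gene expression was profiled in SK-Mel-28 cells 48 h after transfection with 50 nM of a microRNA mimic, on whole-transcriptome Affymetrix Clariom S arrays. There were 11 groups of 3 arrays, 33 in all: 10 human mimics and a control mimic based on a plant microRNA. Per the labels, wells were transfected in triplicate, and the labels do not say whether replicates came from separate cultures. The deposited intensity values were linear and quantile-normalized by the authors, per the name of their sheet, and raw data were processed at a core facility. Background correction, software and the summary of probes were not given in the sources used here. The deposited detection p-values, 1 per probe set and array, came from the authors' sheet. In that sheet, columns name the group but give letters that the labels do not tie to replicates. Only its detection p-values were used, as counts per group, and 99 other columns of values per array were not used.

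The plan had assumed log2 values. Because the deposited intensities were linear, log2 was taken here before fitting, with no pseudocount. Of 27189 probe sets, 21448 had a symbol, 5741 had none, and the symbols of 1319 probe sets were updated to the reference by gene identifier or synonym. Where 1 of 1328 symbols had several probe sets, the one with the highest mean was used, giving 19505 genes. Of all probe sets with a symbol, 969 were assigned to several symbols, and for 1184 genes the assignment field was not used, so whether their probe sets hold other symbols was not checked. Stated positions overlapped the GRCh38 position for 99.2% of 19359 genes compared. Array medians of intensity lay between 224.6 and 235, and 16014 genes were detected on all arrays and 102 on none. Log2 changes over all genes had a median SE of 0.119 per mimic.

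Each mimic, and the mean of the 10 mimics, was compared with the control in a group-means model over all 33 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided). Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. NT5E was also adjusted over its 10 comparisons and tested by exact two-sided permutation. A total of 21 gene lists written before the data were examined were tested with camera (two-sided, preset correlation 0.01), with adjustment over the 21 lists. They covered adenosine, interferon, NF-kB, pigment cell, invasive melanoma, TGF-beta, AP-1, MAPK, hypoxia, DNA replication, mitosis, p53, unfolded protein and integrated stress response, cholesterol, class I antigen presentation, immune checkpoint and NK ligand, microRNA machinery and apoptosis genes. The others held leukocyte, epithelial and fibroblast markers. Some lists share members, such as JUNB in the AP-1 and TGF-beta lists and TGFBI in the invasive melanoma and TGF-beta lists. Shared calls between mimics were set beside 20 simulations of unchanged groups against a shared simulated control. Correlations across the 10 mimics used 100000 permutations. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, data.table (version 1.17.8) and matplotlib 3.10.9 were used.

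A rule written before the data were examined named, for each mimic, NT5E, the 8 genes with the largest increase and the 8 with the largest decrease, and up to 4 members of each list with a member past the threshold. The 16 had to pass the threshold, have all mimic arrays beyond all control arrays, be brighter than the median gene in the higher group and carry an official-looking symbol. For the mean of 10 mimics all group means had to lie beyond the control mean. Up to 10 genes per direction called with the most mimics were named as well. The rule gave 694 pairs of gene and comparison besides NT5E. To keep the text short, the first 4 genes per direction and the first 2 members per shifted list and of the adenosine list were selected for the text, 214 pairs, of which 2 are not reported here. This shortening was set after values had been seen, and the outcome of the alternatives is given for all 694.

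The method was tested on simulated data built on 19505 genes. Per comparison it recovered 3 to 11.9% of genes with a true log2 change of 0.25, 38.8 to 62.7% at 0.5 and 89.4 to 97% at 1, with 3 to 9 false calls. Only 200 genes were changed per simulated comparison, fewer than were called with any mimic. Recovery under the adjustment depends on that number, so it may differ in these data. A list shifted by 0.2 was recovered in 10 of 10 simulated comparisons, and 2 unshifted lists were called. The simulated genes were independent, while the estimated correlation was 0.093 in the mitosis list, so false list calls were not tested at such correlations. Residuals of arrays with the same replicate number had correlations from -0.135 to 0.128 over 165 pairs (median 0.002), so the numbers were not treated as pairs. Alternatives were cyclic loess, median centring, leaving out genes below the 40th percentile of the mean, trend and robust moderation, array weights, a replicate block, averages of probe sets, only the 6 arrays compared, the other mimics as reference, a 2-fold threshold, an estimated correlation between list genes, and leaving out 1 array. A scan of 3′ untranslated regions for 7-base matches to the mimics was planned and not run, because no sequence reference was used here.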

Results

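Gene expression was measured in SK-Mel-28 cells, an established human melanoma line, 48 h after transfection with 50 nM of a synthetic microRNA mimic. A mimic is a short double-stranded RNA that stands in for a mature microRNA. The series held 10 human mimics and a control mimic based on a plant microRNA with no intended human target, with 3 arrays in each of the 11 groups, 33 arrays in all. According to the series design, the mimics were chosen because they enhance expression of NT5E, and each was compared with the control mimic. NT5E encodes the cell surface enzyme CD73, which converts extracellular AMP to adenosine. The values were linear probe set intensities from a whole-transcriptome array, with 1 value per gene for 19505 genes. Of all gene and array pairs, 93.4% were detected at a detection p below 0.05. Correlations of log2 intensities lay between 0.9855 and 0.9906 within groups and between 0.9781 and 0.9887 across groups. The number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples. Changes are log2 differences from the control mimic with the standard error (SE) of the limma fit over 33 arrays, with n = 3 per group, and adjusted p-values are from limma or camera with Benjamini-Hochberg adjustment.

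NT5E was higher with all 10 mimics than with the control mimic. The gene lies on chromosome 6 from 85449584 to 85495791 on the plus strand (GRCh38). Its mean intensity was 3548 ± 51 (SD, n = 3) with the control and 5380 ± 150 with miR-3126-5p, the highest of the groups, a change of 0.60 ± 0.049 or 1.52-fold (adjusted p = 3.14e-09). The change was 0.50 with miR-134-3p, 0.46 with miR-6514-3p, 0.44 with miR-3116, 0.41 with miR-6859-3p and 0.39 with miR-4672, with the same SE of 0.049. It was 0.36 with miR-224-3p, 0.36 with miR-1293, 0.33 with miR-34b-3p and 0.32 with miR-127-5p, the smallest, with an adjusted p of 0.00012. The lowest mimic array, at 4185 with miR-127-5p, lay above the highest control array at 3607. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1 for each mimic, the smallest value this design allows. NT5E ranked between 178 and 812 among all genes by the size of its increase. When the fit held only the 6 arrays compared, the adjusted p was 0.0718 for miR-4672, 0.0787 for miR-6859-3p, 0.194 for miR-34b-3p, 0.134 for miR-1293 and 0.157 for miR-127-5p. Against the mean of the other 9 mimics, NT5E was higher with miR-3126-5p by 0.21 ± 0.036 (adjusted p = 0.000309), and the other 9 differences, from -0.11 to 0.09, did not pass over all genes. Adjusted over the 10 NT5E comparisons alone, the differences of miR-134-3p (0.09, adjusted p = 0.0472), miR-34b-3p (-0.09, adjusted p = 0.0472) and miR-127-5p (-0.11, adjusted p = 0.0321) passed as well.

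**Figure D1:**
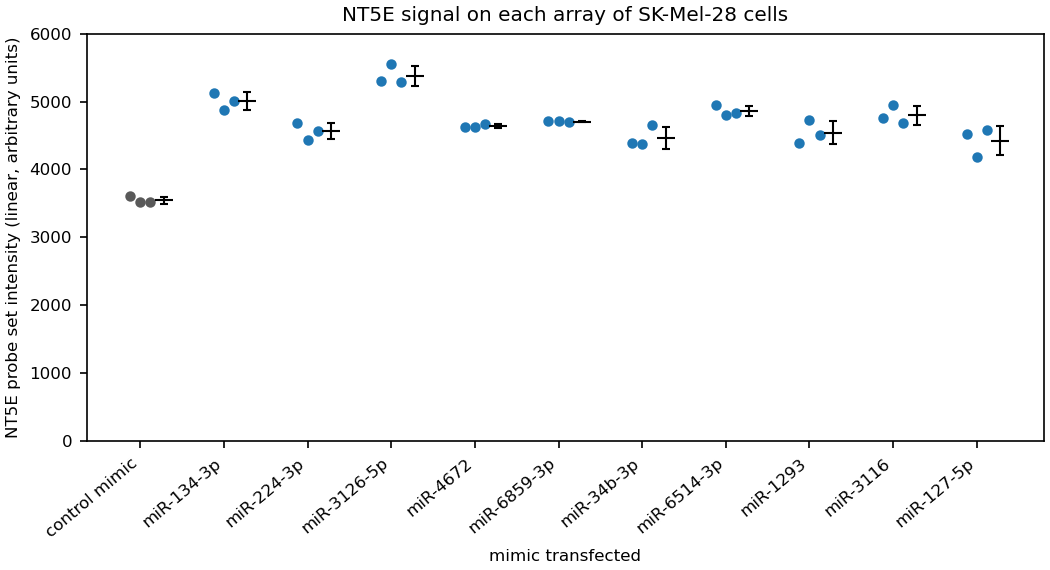
NT5E probe set intensity (linear, arbitrary units) on each of the 33 arrays by mimic, with dots for arrays and a dash with bars for the mean and SD of 3 arrays. All mimic arrays lie above the control arrays, whose mean is 3548, and miR-3126-5p has the highest mean at 5380.

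Other genes of adenosine metabolism and signalling did not move together. The list held 19 measured members, NT5E included, and was not shifted with any mimic, with adjusted camera p-values from 0.276 to 0.982. ENTPD1 (CD39), which hydrolyses ATP and ADP to AMP, rose with miR-134-3p by 0.46 ± 0.09. It also rose with miR-224-3p by 0.31 ± 0.09, but the adjusted p was 0.165 without control replicate 1, 0.0528 without control replicate 3 and 0.157 without miR-224-3p replicate 3. With miR-6514-3p its rise of 0.29 ± 0.09 had adjusted p-values from 0.0787 to 0.238 without control replicates 1 or 3 or without any 1 of the miR-6514-3p replicates. SLC29A1, a nucleoside transporter, fell by 0.92 on the log2 scale with miR-3126-5p (SE 0.18) and by 0.84 with miR-3116 (SE 0.18). ADA, which deaminates adenosine, fell with miR-4672 by 0.51 (SE 0.12), with adjusted p-values of 0.0632 without control replicate 1, 0.0513 without control replicate 2 and 0.0685 without miR-4672 replicate 2. ADK, which phosphorylates adenosine, fell with miR-127-5p by 0.50 (SE 0.06) on a probe set assigned to more than 1 symbol, and the change was -0.19 with an adjusted p of 0.0943 when probe sets of a symbol were averaged. Adjusted over all genes, 3 members rose and 1 fell with miR-134-3p, against 4 and 1 adjusted over the list alone. With miR-224-3p 2 rose and 3 fell under both adjustments, and with miR-3126-5p 2 rose and 2 fell under both.

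With miR-134-3p, cell cycle genes fell and hypoxia genes rose. Of 25 measured DNA replication genes 23 fell, 24 adjusted over the list alone, with a mean change of -0.609 (adjusted p = 1.54e-32). CCNE1, a cyclin of the start of S phase, fell by 0.87 (SE 0.08), and FEN1, a nuclease that processes Okazaki fragments, by 0.67 (SE 0.06). Of 23 mitosis genes 22 fell under both adjustments, with a mean of -0.622 (adjusted p = 3.63e-31). CCNA2, which encodes cyclin A2, fell by 0.76 (SE 0.06) and PLK1, a mitotic kinase, by 0.60 (SE 0.06). Of 22 hypoxia genes 7 rose and 1 fell, 10 and 1 adjusted over the list alone, with a mean of 0.21 (adjusted p = 4.98e-06). VEGFA, an angiogenic growth factor, rose by 0.78 ± 0.09. P4HA2, a collagen prolyl hydroxylase, rose by 0.43 ± 0.05, a call that was lost when probe sets of a symbol were averaged (0.07, adjusted p = 0.6).

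Of 15 AP-1 and immediate early genes 3 rose with miR-134-3p, 4 adjusted over the list alone, with an adjusted p of 0.00201, and of 0.077 with an estimated correlation. The transcription factor gene EGR1 rose by 0.97 ± 0.13 and IER2 by 0.68 ± 0.10. Of 17 MAPK pathway output genes 6 rose and 2 fell, 9 and 3 adjusted over the list alone (adjusted p = 0.00604, and adjusted p = 0.077 with an estimated correlation). SPRY1, a feedback inhibitor of the pathway, rose by 0.53 ± 0.06, and the transcription factor gene ETV4 fell by 0.82 (SE 0.10). Of 28 interferon-stimulated genes 5 fell and 1 rose under both adjustments, with a mean of -0.167 (adjusted p = 0.0148, and adjusted p = 0.077 with an estimated correlation). Without miR-134-3p replicate 2 this list had an adjusted p of 0.0521. IFIT3 fell by 0.83 (SE 0.16) and HERC5 by 0.42 (SE 0.09). The largest single increases were TUBB2A, a beta tubulin, at 1.39 ± 0.25, PLEKHA4 at 1.36 ± 0.31, VGF, a neuropeptide precursor, at 1.34 ± 0.15, and GLRX, a glutaredoxin, at 1.22 ± 0.20. The lowest changes were the histone gene H3C8 at -1.43 ± 0.16, DCTN6, a dynactin subunit, at -1.35 ± 0.10, SELENON at -1.35 ± 0.08 and the histone gene H2AC20 at -1.29 ± 0.33. H2AC20 had an adjusted p of 0.0895 without miR-134-3p replicate 2. In all, 1885 genes changed, 776 higher and 1109 lower, and 31 of them changed at least 2-fold. A fit to only the 6 arrays called 462.

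With miR-224-3p, cell cycle and cholesterol synthesis genes fell and hypoxia genes rose. Among the DNA replication genes 19 of 25 fell, 22 adjusted over the list alone, with a mean of -0.463 (adjusted p = 9.23e-23). DTL, a subunit of a replication-coupled ubiquitin ligase, fell by 0.80 (SE 0.08) and FEN1 by 0.54 (SE 0.06). Among the mitosis genes 21 of 23 fell, all 23 adjusted over the list alone, with a mean of -0.507 (adjusted p = 1.55e-23). TOP2A, a DNA topoisomerase, fell by 0.59 (SE 0.06) and CCNA2 by 0.58 (SE 0.06). Of 20 cholesterol synthesis genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone, with a mean of -0.222 (adjusted p = 8.79e-05). With an estimated correlation the adjusted camera p of this list was 0.0305. The enzyme gene MSMO1 fell by 0.51 (SE 0.10). Among the hypoxia genes 7 of 22 rose, 8 adjusted over the list alone, with a mean of 0.198 (adjusted p = 9.9e-07). The glucose transporter gene SLC2A3 rose by 0.97 ± 0.07. P4HA2 rose by 0.35 ± 0.05, a call that was lost when probe sets of a symbol were averaged (0.12, adjusted p = 0.366).

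Of the AP-1 and immediate early genes 2 of 15 rose with miR-224-3p, 3 adjusted over the list alone (adjusted p = 0.00493, and adjusted p = 0.139 with an estimated correlation). The list had an adjusted p of 0.056 without miR-224-3p replicate 2. JUN, an AP-1 subunit, rose by 0.90 ± 0.14. JUND rose by 0.40 ± 0.10, with adjusted p-values of 0.0896 without miR-224-3p replicate 2 and 0.0565 without control replicate 3. The largest increases were TUBB2A at 1.57 ± 0.25, GLRX at 1.36 ± 0.20, WBP1L at 1.34 ± 0.14 and VGF at 1.17 ± 0.15. At the other end were BANF1, a chromatin-binding protein of the nuclear envelope, at -1.41 ± 0.12, ARPC5, a subunit of the actin-nucleating Arp2/3 complex, at -1.40 ± 0.09, and REXO5, an RNA exonuclease, at -1.32 ± 0.41. REXO5 had adjusted p-values from 0.0797 to 0.169 without any 1 of the control replicates and without miR-224-3p replicates 1 or 3. In all, 1650 genes changed, 739 higher and 911 lower (838 and 799 after median centring), and 21 changed at least 2-fold. A fit to only the 6 arrays called 538.

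With miR-3126-5p, all 23 mitosis genes fell under both adjustments, with a mean of -0.849, the lowest list mean of any mimic. The adjusted camera p was 3.76e-42, and 1.63e-07 with an estimated correlation. PLK1 fell by 1.39 (SE 0.06), to 0.382 of its control level, and CCNA2 by 0.93 (SE 0.06). In the DNA replication list 23 of 25 fell, all 25 adjusted over the list alone, with a mean of -0.714 (adjusted p = 8.9e-38). MCM7, a subunit of the replicative helicase, fell by 0.77 (SE 0.05) and FEN1 by 0.78 (SE 0.06). In the hypoxia list 11 of 22 rose under both adjustments, with a mean of 0.328 (adjusted p = 1.63e-10). VEGFA rose by 1.04 ± 0.09, and PFKFB4, a glycolytic regulator on a probe set assigned to more than 1 symbol, by 0.81 ± 0.09. Of 20 genes of the unfolded protein and integrated stress response 7 rose and 1 fell, 8 and 1 adjusted over the list alone, with a mean of 0.248 (adjusted p = 0.00016). TRIB3, a stress-induced pseudokinase, rose by 0.77 ± 0.08 and DNAJB9, a chaperone of the endoplasmic reticulum, by 0.60 ± 0.08.

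Signalling and inflammatory lists also rose with miR-3126-5p. Some of these lists share members: FOSL1 is in the invasive and AP-1 lists, and IER3 in the MAPK and AP-1 lists. Their calls are therefore not independent. Of 15 TGF-beta targets 3 rose, 4 adjusted over the list alone (adjusted p = 0.00567). CCN2, a matricellular protein, rose by 0.73 ± 0.09 and the receptor gene TGFBR1 by 0.28 ± 0.06. Of the MAPK pathway output genes 5 rose and 2 fell, 8 and 2 adjusted over the list alone (adjusted p = 0.00198). SPRY1 and SPRY4 rose by 0.58 ± 0.06 and 0.54 ± 0.08. Of 16 NF-kB and inflammatory genes 2 rose, 3 adjusted over the list alone (adjusted p = 0.015). The adjusted camera p was 0.0488 with an estimated correlation and 0.0993 without dim genes. The adhesion molecule gene ICAM1 rose by 0.75 ± 0.11 and the cytokine gene IL1B by 0.90 ± 0.21. Of 17 genes of the invasive melanoma state 5 rose under both adjustments (adjusted p = 0.0107, and adjusted p = 0.0829 with an estimated correlation). FOSL1, an AP-1 subunit, rose by 0.34 ± 0.08. NRG1, a growth factor, rose by 0.28 ± 0.07, with adjusted p-values of 0.0516 without miR-3126-5p replicate 1, 0.086 without replicate 2 and 0.0807 without control replicate 3.

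Of the AP-1 and immediate early genes 3 of 15 rose with miR-3126-5p under both adjustments, IER3 among them by 0.32 ± 0.06 (adjusted p = 0.0404 for the list, and adjusted p = 0.22 with an estimated correlation). The list had adjusted p-values of 0.0803 without control replicate 1, 0.054 without miR-3126-5p replicate 1 and 0.133 without miR-3126-5p replicate 2. Of 17 class I antigen presentation genes 1 rose and 1 fell under both adjustments (adjusted p = 0.0369, and adjusted p = 0.0839 with an estimated correlation). That list had adjusted p-values of 0.0688 without control replicate 1, 0.0513 without miR-3126-5p replicate 1 and 0.0501 without control replicate 3. The class I gene HLA-F rose by 0.48 ± 0.08, and was -0.05 against the mean of the other 9 mimics. The immunoproteasome subunit gene PSMB9 fell by 0.26 (SE 0.08), with adjusted p-values of 0.129 without control replicate 2, 0.097 without control replicate 3, 0.231 without miR-3126-5p replicate 2 and 0.0643 with array weights. The largest increases were CEMIP, a hyaluronan-binding protein, at 1.81 ± 0.22, TUBB2A at 1.44 ± 0.25, GLRX at 1.39 ± 0.20 and NINJ1, a membrane protein of cell rupture, at 1.15 ± 0.27. The largest decreases were the histone gene H3C7 at -1.97 ± 0.51, REXO5 at -1.77 ± 0.41, the readthrough gene RPS10-NUDT3 at -1.73 ± 0.15 and H2AC20 at -1.59 ± 0.33. In all, 2154 genes changed, 990 higher and 1164 lower, the most of any mimic, and 51 changed at least 2-fold. A fit to only the 6 arrays called 857.

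With miR-4672, pigment cell genes rose, and MAPK pathway output, interferon-stimulated and cell cycle genes fell. Of 20 pigment cell genes 6 rose, 7 adjusted over the list alone, with a mean of 0.2 (adjusted p = 6.46e-07). TRPM1, a cation channel of melanocytes, rose by 0.85 ± 0.12 and EDNRB, the endothelin B receptor, by 0.52 ± 0.08. Of the MAPK pathway output genes 3 of 17 fell, 7 adjusted over the list alone, with a mean of -0.169 (adjusted p = 0.000244). The feedback inhibitor genes SPRED2 and DUSP6 fell by 0.53 (SE 0.09) and 0.59 (SE 0.10). Of the interferon-stimulated genes 4 of 28 fell, 7 adjusted over the list alone (adjusted p = 0.000244). IFIT1 and IFIT3 fell by 0.82 (SE 0.12) and 0.93 (SE 0.16). Of the DNA replication genes 11 of 25 fell, 14 adjusted over the list alone, with a mean of -0.262 (adjusted p = 9.9e-11). The helicase subunit gene MCM6 fell by 0.66 (SE 0.10) and CDC6, which loads that helicase, by 0.38 (SE 0.07). In the mitosis list 5 of 23 fell, 7 adjusted over the list alone, with a mean of -0.257 (adjusted p = 3.22e-09). PLK1 fell by 0.93 (SE 0.06) and AURKB, a mitotic kinase, by 0.53 (SE 0.09). Against the mean of the other 9 mimics the CDC6 difference was 0.16, of the opposite sign.

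4 further lists were shifted with miR-4672, and each was lost with an estimated correlation. Of the cholesterol synthesis genes 3 of 20 rose, 5 adjusted over the list alone with 1 lower (adjusted p = 0.00217, and adjusted p = 0.0713 with an estimated correlation). MSMO1 rose by 0.67 ± 0.10 and LSS, lanosterol synthase, by 0.57 ± 0.11. Of 20 p53 targets 4 fell, 6 adjusted over the list alone (adjusted p = 0.00566, and adjusted p = 0.0713 with an estimated correlation). The DNA repair gene DDB2 fell by 0.78 (SE 0.15). PHLDA3 fell by 0.31 (SE 0.08), with adjusted p-values from 0.0526 to 0.125 without control replicates 2 or 3 and without miR-4672 replicates 1 or 3. Of the hypoxia genes 3 of 22 rose, 7 adjusted over the list alone with 1 lower (adjusted p = 0.014, and adjusted p = 0.136 with an estimated correlation). This list had an adjusted p of 0.0534 without control replicate 3. PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 0.33 ± 0.06. EGLN3, an oxygen-sensing hydroxylase, rose by 0.67 ± 0.16, with adjusted p-values of 0.0735 without control replicate 3 and 0.0736 without miR-4672 replicate 3. Of the invasive melanoma genes 2 of 17 fell, 3 adjusted over the list alone (adjusted p = 0.0363, and adjusted p = 0.147 with an estimated correlation). That list had adjusted p-values of 0.145 without control replicate 1 and 0.118 without miR-4672 replicate 3. NRG1 fell by 0.54 (SE 0.07) and the transcription factor gene ZEB1 by 0.39 (SE 0.09).

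The largest increases with miR-4672 were PASK, a nutrient-sensing kinase, at 1.18 ± 0.28, ABCB5, a transporter, at 1.05 ± 0.13, SCUBE2 at 0.95 ± 0.10 and GALNT3, a glycosyltransferase, at 0.94 ± 0.10. PASK had an adjusted p of 0.0583 without miR-4672 replicate 2. The lowest changes were LIMK1, a kinase of cofilin, at -1.16 ± 0.17, MCM3AP at -1.13 ± 0.29, ATG4D, an autophagy protease, at -1.07 ± 0.07 and PTBP3, an RNA-binding protein, at -1.06 ± 0.13. MCM3AP had adjusted p-values of 0.117 without control replicate 2, 0.0659 without miR-4672 replicate 2 and 0.0542 with array weights. In all, 1145 genes changed, 503 higher and 642 lower, and 13 changed at least 2-fold. The number was 725 without control replicate 2, 85 in a fit to only the 6 arrays and 2099 against the mean of the other 9 mimics.

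With miR-6859-3p, cell cycle genes fell. Of the mitosis genes 14 of 23 fell, 18 adjusted over the list alone, with a mean of -0.376 (adjusted p = 1.04e-19). CCNA2 fell by 0.59 (SE 0.06) and PRC1, which bundles microtubules of the spindle midzone, by 0.61 (SE 0.07). Among the DNA replication genes 10 of 25 fell, 17 adjusted over the list alone, with a mean of -0.286 (adjusted p = 3.82e-14). CDC6 fell by 0.70 (SE 0.07). FEN1 fell by 0.34 (SE 0.06), while against the mean of the other 9 mimics its difference was 0.17, of the opposite sign. Of the pigment cell genes 3 of 20 rose, 4 adjusted over the list alone (adjusted p = 0.0121, and adjusted p = 0.169 with an estimated correlation). TRPM1 rose by 0.60 ± 0.12. GPR143, a receptor of melanosomes, rose by 0.24 ± 0.06, with adjusted p-values of 0.0683 without control replicate 1 and 0.0653 without miR-6859-3p replicate 2.

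The largest increases with miR-6859-3p were TUBB2A at 1.23 ± 0.25, TMEM64 at 1.13 ± 0.05, PASK at 0.93 ± 0.28 and the keratin gene KRT17 at 0.87 ± 0.21. PASK had adjusted p-values from 0.0881 to 0.173 without control replicates 2 or 3 or without any 1 of the miR-6859-3p replicates, 0.0902 with array weights and 0.0504 with averaged probe sets. KRT17 had adjusted p-values of 0.119 without control replicate 2 and 0.0709 without miR-6859-3p replicate 3. At the other end were PLAAT3, a phospholipase, at -1.53 ± 0.10, REXO5 at -1.42 ± 0.41, ZMAT2 at -1.18 ± 0.09 and POLR2F, an RNA polymerase subunit on a probe set assigned to more than 1 symbol, at -1.17 ± 0.07. REXO5 had adjusted p-values from 0.0833 to 0.137 without any 1 of the 6 arrays and 0.0571 with array weights. In all, 947 genes changed, 377 higher and 570 lower, and 11 changed at least 2-fold. The number was 586 without control replicate 2 and 66 in a fit to only the 6 arrays.

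With miR-34b-3p, cholesterol synthesis and cell cycle genes fell, and the fewest genes of any mimic changed. Of the cholesterol synthesis genes 4 of 20 fell, 8 adjusted over the list alone, with a mean of -0.253 (adjusted p = 1.94e-09). MSMO1 fell by 0.67 (SE 0.10) and DHCR7, which makes the last step to cholesterol, by 0.40 (SE 0.08). In the DNA replication list 6 of 25 fell, 17 adjusted over the list alone, with a mean of -0.283 (adjusted p = 4.71e-16). FEN1 fell by 0.47 (SE 0.06) and CDC6 by 0.45 (SE 0.07). Among the mitosis genes 6 of 23 fell, 13 adjusted over the list alone, with a mean of -0.226 (adjusted p = 3.46e-10). TOP2A fell by 0.28 (SE 0.06), with adjusted p-values of 0.0558 without control replicate 1, 0.0837 without control replicate 2 and 0.0775 without miR-34b-3p replicate 1. CCNA2 fell by 0.27 (SE 0.06), with adjusted p-values from 0.0723 to 0.111 without control replicates 1 or 3 and without miR-34b-3p replicates 1 or 3. Against the mean of the other 9 mimics, these genes had the opposite sign, at 0.03 for FEN1, 0.09 for CDC6, 0.16 for TOP2A and 0.21 for CCNA2.

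Among the hypoxia genes 2 of 22 rose with miR-34b-3p, 6 adjusted over the list alone, with a mean of 0.136 (adjusted p = 2.46e-06). P4HA2 rose by 0.27 ± 0.05, a call that was lost with averaged probe sets (0.03, adjusted p = 0.915). VEGFA rose by 0.36 ± 0.09, with adjusted p-values from 0.0788 to 0.117 without control replicates 2 or 3 and without miR-34b-3p replicates 1 or 2, and it was -0.17 against the mean of the other 9 mimics. Of the pigment cell genes none passed over all genes and 2 were higher adjusted over the list alone, with a mean of 0.071 (adjusted p = 0.0229, and adjusted p = 0.181 with an estimated correlation). That list had adjusted p-values of 0.102 without miR-34b-3p replicate 1 and 0.0699 without control replicate 2. The largest increases were TUBB2A at 1.41 ± 0.25, WBP1L at 1.33 ± 0.14, PASK at 1.14 ± 0.28 and RBPJ, the Notch pathway transcription factor, at 1.03 ± 0.22. PASK had adjusted p-values from 0.0766 to 0.127 without control replicates 2 or 3 and without miR-34b-3p replicates 1 or 2, and RBPJ of 0.0678 without control replicate 2. The largest decreases were TLNRD1 at -1.21 ± 0.21, DENND6A at -0.97 ± 0.06, ACAA2, a mitochondrial thiolase, at -0.81 ± 0.21, and ALG11, a glycosyltransferase on a probe set assigned to more than 1 symbol, at -0.79 ± 0.18. ACAA2 had adjusted p-values from 0.0505 to 0.208 without control replicates 2 or 3 or without any 1 of the miR-34b-3p replicates, and of 0.0559 with array weights. ALG11 had adjusted p-values from 0.0511 to 0.0963 without control replicates 1 or 2 and without miR-34b-3p replicates 1 or 3. In all, 361 genes changed, 122 higher and 239 lower, and 7 changed at least 2-fold. The number was 209 without control replicate 2, 188, 207 and 236 without miR-34b-3p replicates 1, 2 and 3, and 3 in a fit to only the 6 arrays.

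With miR-6514-3p, cholesterol synthesis genes rose and DNA replication genes fell. Of the cholesterol synthesis genes 12 of 20 rose, 13 adjusted over the list alone, with a mean of 0.435 (adjusted p = 2.04e-14). HMGCS1, an early enzyme of the pathway, rose by 1.41 ± 0.10, or 2.65-fold, and MSMO1 by 0.92 ± 0.10. Of the DNA replication genes 22 of 25 fell, 23 adjusted over the list alone, with a mean of -0.548 (adjusted p = 1.78e-28). RRM1, a subunit of ribonucleotide reductase, fell by 1.03 (SE 0.06) and FEN1 by 0.82 (SE 0.06). In the mitosis list 14 of 23 fell, 17 adjusted over the list alone, with a mean of -0.387 (adjusted p = 2.77e-15). TOP2A fell by 0.58 (SE 0.06) and PRC1 by 0.49 (SE 0.07). Of the unfolded protein and integrated stress response genes 7 of 20 rose, 8 adjusted over the list alone, with a mean of 0.249 (adjusted p = 4.1e-06). HERPUD1, a protein of endoplasmic reticulum degradation, rose by 0.85 ± 0.11 and TRIB3 by 0.59 ± 0.08.

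In the hypoxia list 5 of 22 rose with miR-6514-3p, 6 adjusted over the list alone (adjusted p = 0.000866, and adjusted p = 0.0567 with an estimated correlation). SLC2A3 rose by 0.41 ± 0.07 and PDK1 by 0.30 ± 0.06. Of the pigment cell genes 5 rose and 1 fell, 6 and 1 adjusted over the list alone (adjusted p = 0.0266, and adjusted p = 0.179 with an estimated correlation). That list had an adjusted p of 0.0677 without control replicate 2. ST3GAL6, a sialyltransferase, rose by 0.49 ± 0.09, with an adjusted p of 0.0672 when probe sets were averaged, and OCA2, a melanosomal transporter, by 0.25 ± 0.06. Besides HMGCS1, the largest increases were TUBB2A at 1.57 ± 0.25, GLRX at 1.26 ± 0.20 and DPH3 at 1.21 ± 0.22. The lowest changes were H3C7 at -1.80 ± 0.51, REXO5 at -1.69 ± 0.41, RPS10-NUDT3 at -1.58 ± 0.15 and POMK, a kinase of protein glycosylation, at -1.41 ± 0.11. H3C7 had adjusted p-values from 0.0512 to 0.0714 without any 1 of the 6 arrays. In all, 1806 genes changed, 778 higher and 1028 lower (925 and 855 after median centring), and 25 changed at least 2-fold. A fit to only the 6 arrays called 703.

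With miR-1293, stress response genes rose and ligands of immune receptors fell, while the replication and mitosis lists did not pass. Of the unfolded protein and integrated stress response genes 5 of 20 rose, 6 adjusted over the list alone, with a mean of 0.215 (adjusted p = 4e-06). TRIB3 rose by 0.64 ± 0.08 and DNAJB9 by 0.53 ± 0.08. Of 18 immune checkpoint and NK ligand genes 4 fell, 5 adjusted over the list alone, with a mean of -0.238 (adjusted p = 0.000333). MICB, a ligand of the NK cell receptor NKG2D, fell by 0.56 (SE 0.07) and PVR, the poliovirus receptor, by 0.68 (SE 0.10). Of the hypoxia genes 6 rose and 1 fell under both adjustments, with a mean of 0.15 (adjusted p = 0.000138). VEGFA rose by 0.46 ± 0.09, and was -0.05 against the mean of the other 9 mimics. DDIT4, a stress-induced inhibitor of mTOR, rose by 0.42 ± 0.08. Of the MAPK pathway output genes 3 of 17 rose, 4 adjusted over the list alone (adjusted p = 0.00962, and adjusted p = 0.0899 with an estimated correlation). SPRED1 rose by 0.55 ± 0.06 and IER3 by 0.37 ± 0.06.

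Of 17 genes of the microRNA machinery 1 rose and 1 fell with miR-1293, 5 and 2 adjusted over the list alone (adjusted p = 0.0477, and adjusted p = 0.13 with an estimated correlation). The list had adjusted p-values of 0.234 without miR-1293 replicate 1, 0.0671 without control replicate 2 and 0.0912 without control replicate 3. TNRC6A, a silencing scaffold, rose by 0.38 ± 0.10, with adjusted p-values from 0.0724 to 0.173 without control replicates 1 or 2 and without miR-1293 replicates 1 or 2. AGO1, an Argonaute, fell by 0.25 (SE 0.07), with adjusted p-values from 0.0567 to 0.176 without control replicates 1 or 3 or without any 1 of the miR-1293 replicates. It was also lost after cyclic loess (adjusted p = 0.0515) and median centring (adjusted p = 0.0687). The histone gene H4C12 was called higher, but it was detected on 0 control arrays and 2 miR-1293 arrays, so neither size nor rank is given. The largest increases besides were WBP1L at 1.12 ± 0.14, LINC03048, on a probe set assigned to more than 1 symbol, at 1.09 ± 0.25 and PHLDA2 at 0.92 ± 0.23. H4C12 had adjusted p-values from 0.0542 to 0.197 without control replicates 1 or 3 or without any 1 of the miR-1293 replicates. LINC03048 had adjusted p-values of 0.058 without control replicate 1 and 0.06 without miR-1293 replicate 2, and PHLDA2 of 0.0681 and 0.0627 without miR-1293 replicates 1 and 2. At the other end were GFI1, a transcriptional repressor, at -1.53 ± 0.27, S100A11, a calcium-binding protein, at -1.01 ± 0.07, MRPL14, a mitochondrial ribosomal protein, at -0.99 ± 0.09 and TNFAIP1 at -0.91 ± 0.16. In all, 792 genes changed, 323 higher and 469 lower, and 5 changed at least 2-fold. The number was 513 without control replicate 2, 514 without miR-1293 replicate 2, 6 in a fit to only the 6 arrays and 1824 against the mean of the other 9 mimics.

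With miR-3116, cell cycle genes and p53 targets fell. Of the mitosis genes 21 of 23 fell, all 23 adjusted over the list alone, with a mean of -0.667 (adjusted p = 8.68e-35). CCNA2 fell by 0.77 (SE 0.06) and TOP2A by 0.70 (SE 0.06). Among the DNA replication genes 22 of 25 fell, 24 adjusted over the list alone, with a mean of -0.633 (adjusted p = 1.48e-34). CDC6 fell by 0.94 (SE 0.07) and RRM1 by 0.67 (SE 0.06). Of the p53 targets 5 of 20 fell, 6 adjusted over the list alone, with a mean of -0.214 (adjusted p = 0.000449). MDM2, the ubiquitin ligase of p53, fell by 0.80 (SE 0.08) and AEN, a nuclease, by 0.61 (SE 0.08). Among the hypoxia genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone (adjusted p = 0.000624, and adjusted p = 0.0567 with an estimated correlation). SLC2A3 rose by 0.55 ± 0.07 and the glycolytic enzyme gene ALDOA fell by 0.36 (SE 0.06). Of the pigment cell genes 5 rose and 1 fell, 9 and 1 adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.137 with an estimated correlation). OCA2 rose by 0.30 ± 0.06, and CAPN3, a protease, fell by 0.64 (SE 0.10).

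The largest increases with miR-3116 were TUBB2A at 1.54 ± 0.25, PTBP2, a splicing regulator, at 1.41 ± 0.10, WBP1L at 1.35 ± 0.14 and TMEM64 at 0.96 ± 0.05. The 4 largest decreases were all histone genes, H3C8 at -1.44 ± 0.16, H3C10 at -1.31 ± 0.25, H2BC11 at -1.28 ± 0.17 and H2AC20 at -1.20 ± 0.33. H2AC20 had adjusted p-values from 0.0524 to 0.128 without control replicates 2 or 3 and without miR-3116 replicates 1 or 3. Histone genes of the same family can be near-identical copies, so which copy changed is uncertain, and cross-hybridisation between copies was not measured. In all, 1743 genes changed, 747 higher and 996 lower, and 32 changed at least 2-fold. A fit to only the 6 arrays called 536.

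With miR-127-5p, hypoxia and stress response genes rose and DNA replication genes fell. In the hypoxia list 7 of 22 rose, 13 adjusted over the list alone, with a mean of 0.273 (adjusted p = 1.92e-14). VEGFA rose by 0.86 ± 0.09 and BNIP3, a mitophagy receptor, by 0.50 ± 0.06. Of the unfolded protein and integrated stress response genes 4 of 20 rose, 7 adjusted over the list alone with 2 lower (adjusted p = 0.000632). SLC7A11, the cystine transporter, rose by 0.58 ± 0.09 and the lipoprotein receptor gene VLDLR by 0.61 ± 0.11. In the DNA replication list 2 of 25 fell, MCM7 by 0.32 (SE 0.05) and FEN1 by 0.32 (SE 0.06), and 7 fell adjusted over the list alone (adjusted p = 9.78e-07). Against the mean of the other 9 mimics the differences were 0.06 for MCM7 and 0.19 for FEN1, of the opposite sign. The largest increases were GLRX, 2.82-fold higher, TUBB2A at 1.23 ± 0.25, WBP1L at 1.03 ± 0.14 and INSIG2, a regulator of sterol synthesis, at 1.02 ± 0.15. The largest decreases were BLVRB, a biliverdin reductase, at -1.38 ± 0.11, SLC35A4 at -1.25 ± 0.08, SPDL1, a spindle checkpoint protein, at -1.24 ± 0.15 and H3C10 at -1.16 ± 0.25. In all, 737 genes changed, 347 higher and 390 lower (375 and 346 after median centring), and 13 changed at least 2-fold. The number was 484 without miR-127-5p replicate 2, 83 in a fit to only the 6 arrays and 1460 against the mean of the other 9 mimics, and without control replicate 2 the number of shifted lists was 5 in place of 3.

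**Figure D2:**
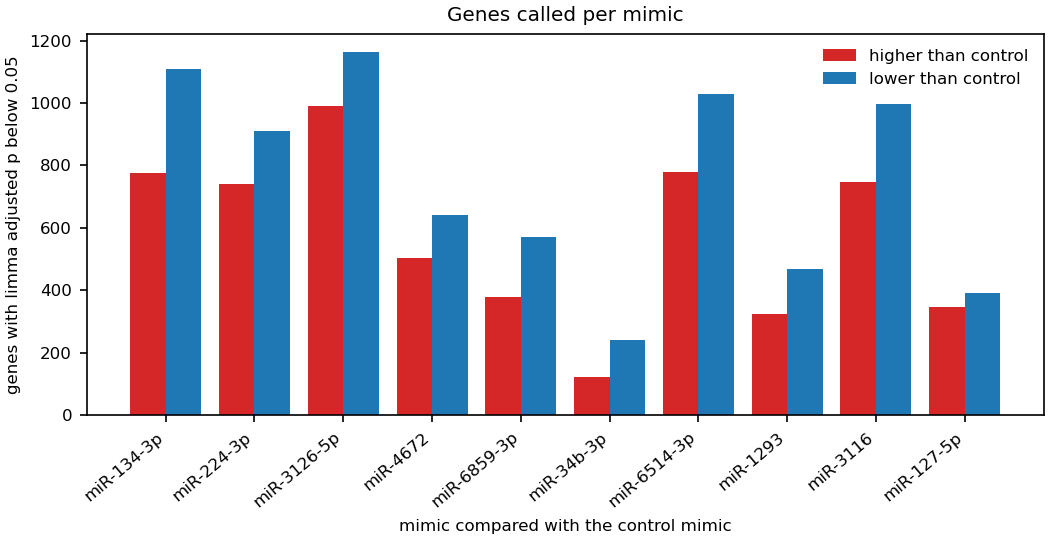
Number of genes with a limma adjusted p below 0.05 for each mimic against the control mimic, with bars for genes higher and lower than control. The counts run from 122 higher and 239 lower with miR-34b-3p to 990 higher and 1164 lower with miR-3126-5p.

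Across mimics, the list calls fell into a few recurring groups. DNA replication genes were lower with 9 mimics and mitosis genes with 8, and these list calls held with an estimated correlation, while several gene ontology terms for replication did not. Hypoxia genes were higher with 9 mimics, of which 6 held. Pigment cell genes were higher with 5, of which 1 held, and the unfolded protein and integrated stress response with 4, which all held. AP-1 and immediate early genes were higher with 3 mimics, none of which held. In 37 of 210 list tests the mean, the median and the direction of the test differed in sign, and none of these was a called list. Against the mean of the other 9 mimics, a test chosen after seeing the data, the DNA replication list was higher with miR-4672 (0.159, adjusted p = 3.28e-05), miR-6859-3p (0.133, 0.000116), miR-34b-3p (0.136, 5.02e-09), miR-127-5p (0.228, 2.13e-14) and miR-1293 (0.387, 1.31e-25), and lower with 4 others. The mitosis list was higher there with miR-4672 (0.15, adjusted p = 0.000603), miR-34b-3p (0.184, 3.36e-12), miR-127-5p (0.367, 5.59e-26) and miR-1293 (0.47, 1.74e-32), and lower with 4 others. The hypoxia list was lower with miR-4672 (-0.063, adjusted p = 0.026) and miR-6859-3p (-0.248, 1.21e-14), and higher with miR-3126-5p (0.186, 5.42e-06) and miR-127-5p (0.125, 1.13e-05). Of these, the replication and mitosis lists with miR-1293 were not called against the control. Nor were the mitosis list with miR-127-5p and the hypoxia list with miR-6859-3p. Other lists too passed against the other 9 mimics alone. Among them, interferon-stimulated genes were higher with miR-34b-3p (0.146, adjusted p = 9.38e-07) and p53 targets with miR-1293 (0.126, 0.00269). Pigment cell genes were lower with miR-134-3p (-0.089, 0.00754), miR-224-3p (-0.116, 0.00196) and miR-3126-5p (-0.084, 0.00364). Against the control, apoptosis regulators had adjusted p-values from 0.234 to 0.982 and were shifted with no mimic. Against the other 9 mimics they were higher with miR-134-3p (0.102, adjusted p = 0.0206). Among markers of other cell types, no list was shifted against the control. The lowest adjusted p there was 0.385 for leukocyte, 0.0981 for epithelial and 0.245 for fibroblast markers.

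**Figure D3:**
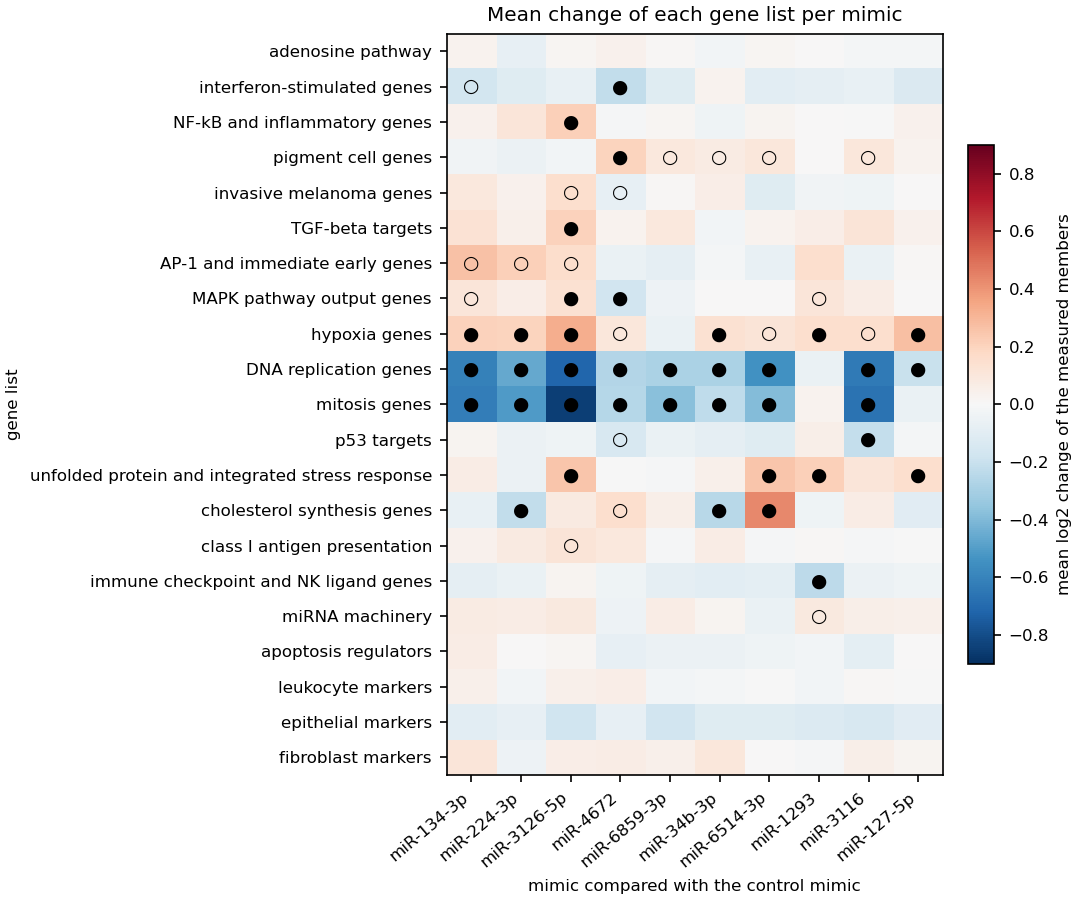
Mean log2 change of the measured members of each of the 21 gene lists (vertical axis) with each mimic against the control (horizontal axis), in colour from blue (lower) to red (higher). Filled circles mark lists called with both a preset and an estimated correlation, and open circles those called with the preset correlation alone. The mitosis list has its lowest mean, -0.849, with miR-3126-5p, and the cholesterol list its highest, 0.435, with miR-6514-3p.

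The mean of the 10 mimics against the control gave average changes, which single mimics need not share: the mitosis list, lower in the mean, was 0.03 with miR-1293. VEGFA was higher by 0.51 ± 0.06 and SLC2A3 by 0.36 ± 0.05, and 8 of 22 hypoxia genes rose, 8 adjusted over the list alone (adjusted p = 3.99e-09). Of the DNA replication genes 22 of 25 fell, 23 adjusted over the list alone, FEN1 by 0.50 (SE 0.05) and RRM1 by 0.42 (SE 0.04) among them (adjusted p = 5.31e-35). Among the mitosis genes 19 of 23 fell, 22 adjusted over the list alone, PLK1 by 0.50 (SE 0.05) and CCNA2 by 0.46 (SE 0.05) among them (adjusted p = 1.35e-30). Of the unfolded protein and integrated stress response genes 5 rose and 1 fell, 7 and 1 adjusted over the list alone (adjusted p = 0.0143, and adjusted p = 0.111 with an estimated correlation), with TRIB3 at 0.38 ± 0.06 and DNAJB9 at 0.34 ± 0.06. The largest increases were TUBB2A at 1.20 ± 0.18, the growth factor gene FGF8 at 0.93 ± 0.26, GLRX at 0.88 ± 0.15 and ZNF283 at 0.83 ± 0.23. With the 8 single mimics for which it is named above, TUBB2A was 0.03 to 0.41 against the mean of the other 9 mimics (adjusted p from 0.188 to 0.959), and in fits to only the 6 arrays compared its adjusted p lay between 0.0638 and 0.288. Against the other 9 mimics GLRX did not pass with miR-134-3p (0.39) and miR-6514-3p (0.43), WBP1L with miR-1293 (0.21) and miR-127-5p (0.10), REXO5 with miR-224-3p (-0.56) and miR-6859-3p (-0.66), and PASK with miR-4672 (0.58), miR-6859-3p (0.30) and miR-34b-3p (0.54). FGF8 was detected on 2 control arrays and was 0.28 (adjusted p = 0.706) without control replicate 2 and 1.08 (adjusted p = 0.059) without control replicate 1. ZNF283 was 0.07 (adjusted p = 0.713) without control replicate 2. With array weights the adjusted p was 0.108 for FGF8 and 0.121 for ZNF283. The lowest changes were the histone genes H2BC11 at -0.85 ± 0.12, H3C10 at -0.83 ± 0.19, H2BC10 at -0.78 ± 0.13 and H2AC4 at -0.77 ± 0.11. H3C10 had an adjusted p of 0.0731 without control replicate 3. SLC29A1 fell by 0.57 (SE 0.13), with adjusted p-values of 0.114 without control replicate 1 and 0.0852 without control replicate 3. In all, 1124 genes changed, 477 higher and 647 lower, 1 of them at least 2-fold, and the number was 513 without control replicate 2.

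Genes called with most mimics were listed by the number of comparisons. A total of 10 genes were higher with all 10 mimics and none was lower with all 10, while 6 were lower with 9. NT5E was among the 10, with a mean change of 0.42. The others included HLA-F (0.53), the syndecan gene SDC4 (0.53) and the transcription factor gene SOX6 (0.43). PRB4, also among the 10, was detected on 1 control array, so no size is given. Lower with 9 mimics were FEN1 (mean -0.50), SDC1, another syndecan (-0.52), and the histone genes H2AC8, H2AC11 and H2AX. A pair of mimics shared a median of 302 genes called in the same direction (89 to 1024). Independent lists would share a median of 39.6, and simulated unchanged groups against a shared simulated control shared 0. Unchanged groups give almost no calls at all, so that 0 was set by the simulation, and 39.6 leaves out the shared control. Neither value is a baseline for 302. A median of 34 genes were called in opposite directions. The median of shared genes was 180 without control replicate 2 and 12 in fits to only the 6 arrays. With the mean of the other 8 mimics as reference, a pair shared a median of 230 genes in the same direction and 150 in opposite directions. The median correlation of changes was then 0.093. Both members of a pair share this reference too, and it was not simulated. So 0.093 is not shown to exceed what a shared reference alone gives. The median correlation of changes across genes was 0.458, beside 0.498 in the simulation, and genes are not independent replicates. The median covariance was 0.01798, beside 0.01044 simulated, a difference of 0.00754. The 3 control arrays were too few to give each comparison controls of its own. Of the 197 single gene changes selected for the 10 mimics, NT5E not counted, 89 did not pass in fits to only the 6 arrays compared.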

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

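The tests of differences between mimics, the fits of probe sets without a gene, the comparison of NT5E with the cell cycle lists and the question of the control mimic lowering NT5E were chosen after results had been seen. The other tests of explanations were set before.

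3 gene lists were called in opposite directions with different mimics, and the difference itself passed a test among 945 (45 pairs of mimics, 21 lists). For the MAPK pathway output genes, miR-3126-5p minus miR-4672 was 0.305 (adjusted p = 1.13e-07, and 0.00169 with an estimated correlation). For cholesterol synthesis, miR-34b-3p minus miR-6514-3p was -0.688 (adjusted p = 1.91e-27, and 1.09e-05). For the invasive melanoma genes, miR-3126-5p minus miR-4672 was 0.225 (adjusted p = 9.77e-05, and 0.0203), although both single calls were lost with an estimated correlation against the control.

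Probe sets outside the gene table also changed. In at least 1 comparison, 467 of 2838 probe sets with no annotation, 747 of 1798 exon and 11 of 407 intron probe sets of normalization genes, and 1 of 63 spike-in (ERCC) probe sets passed. The exon probe sets were called lower more often than higher with each of the 10 mimics, such as 179 lower and 22 higher with miR-127-5p, 101 and 11 with miR-6859-3p and 112 and 33 with miR-224-3p. None of 23 antigenomic background probe sets passed in the same limma fits. No explanation was tested for these.

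NT5E was higher with all 10 mimics than with the control. Without each control array in turn the smallest of the 10 changes was 0.31, which argues against a single deviating control array as the whole cause. It was 0.31 after cyclic loess or median centring too, but these moved the median change of all genes by at most 0.026 on values already normalized, so they could not have ended the pattern, and normalization stays open. Whether the control mimic lowered NT5E stays open, since the design held 0 groups without any mimic. The mimics were chosen by the study for raising NT5E, so a biological explanation is named by the design and was not tested here.

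Of 5682 genes called with any mimic, 176 were higher and 176 lower with at least 6 mimics, while 1248 were higher and 2011 lower with exactly 1. When each of the 11 groups was set against the rest, 10, the control included, had a count at least that of the control. This argues against a control that differs from the rest in more genes than other groups do. The count of a mimic includes its own effects, so an offset of the control, for which 1124 genes passed, stays open. Without control replicate 2 the count for the mean of 10 mimics fell from 1124 to 513, of which 465 were among the 1124. Noise of single control arrays may account for part of the 1124, but a fit with fewer control arrays also has less power. Control replicate 2 had the lowest weight, 0.59. With array weights, which keep that array, 928 genes passed, 904 of them among the 1124. What else separates the control from most mimics was not tested.

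Cell cycle genes were lower with several mimics. The DNA replication list, which holds no histone gene, was called lower in 9 comparisons. As that list is part of the pattern, this shows only that cross-hybridisation among histone copies is not needed for it. Across the 10 mimics, the replication and mitosis list means had r = 0.951 (rho 0.976, permutation p = 4e-05 for both, r = 0.904 without the 2 farthest mimics). As both lists make up the pattern, this describes it and leaves open whether a common shift of proliferation genes lies behind it. The cause was not tested.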

How the results depend on the processing

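Testing the lists against the other 9 mimics was chosen after seeing the data, and no other alternative was. The value table of the authors' sheet was not run, because the labels do not tie the letters of its columns to replicates, nor was the scan of untranslated regions with its alternatives, which had no sequence reference here.

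NT5E kept its direction and passed with all 10 mimics under cyclic loess, median centring, the dim gene filter, trend and robust moderation, array weights and averages, from 0.31 to 0.60, and with any 1 array left out, from 0.29 to 0.61. With only the 6 arrays compared it no longer passed with miR-4672 (0.39, adjusted p = 0.0718), miR-6859-3p (0.41, 0.0787), miR-34b-3p (0.33, 0.194), miR-1293 (0.36, 0.134) and miR-127-5p (0.32, 0.157), where fewer arrays estimate the spread. Against the mean of the other 9 mimics it did not pass with miR-134-3p (0.09), miR-6514-3p (0.04) and miR-3116 (0.02). It turned with miR-224-3p (-0.06), miR-4672 (-0.03), miR-6859-3p (-0.01), miR-34b-3p (-0.09), miR-1293 (-0.07) and miR-127-5p (-0.11), a reference that itself has raised NT5E.

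Also against the other 9 mimics, HLA-F turned with miR-3126-5p (-0.05), CDC6 with miR-4672 (0.16) and FEN1 with miR-6859-3p (0.17). With miR-34b-3p VEGFA (-0.17), FEN1 (0.03), CDC6 (0.09), TOP2A (0.16) and CCNA2 (0.21) turned, with miR-1293 VEGFA (-0.05), and with miR-127-5p MCM7 (0.06) and FEN1 (0.19). In these the other mimics had the larger mean change. Gene counts there moved to 2099 with miR-4672, 1824 with miR-1293 and 1460 with miR-127-5p, and the cause was not tested.

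In the order miR-134-3p, miR-224-3p, miR-3126-5p, miR-4672, miR-6859-3p, miR-34b-3p, miR-6514-3p, miR-1293, miR-3116 and miR-127-5p, the 2-fold threshold left 31, 21, 51, 13, 11, 7, 25, 5, 32 and 13 genes, and 1 for the mean of 10 mimics. Only the 6 arrays gave 462, 538, 857, 85, 66, 3, 703, 6, 536 and 83, and a median of 12 shared genes per pair. Under median centring more genes were higher than lower with miR-224-3p (838 and 799), miR-6514-3p (925 and 855) and miR-127-5p (375 and 346), the opposite of the split without centring. Leaving out 1 array gave 725 to 998 genes for miR-4672, 586 to 795 for miR-6859-3p, 188 to 269 for miR-34b-3p, 513 to 675 for miR-1293, 484 to 643 for miR-127-5p, 513 to 1139 for the mean of 10 mimics, 180 to 264 shared genes and 3 to 5 lists for miR-127-5p. The lowest of miR-4672, miR-6859-3p, miR-1293, the mean and sharing came without control replicate 2, as did 5 lists, and those of miR-34b-3p and miR-127-5p without their replicates 1 and 2. The cause was not tested.

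With an estimated correlation the number of shifted lists was 3 for miR-134-3p, 5 for miR-4672, 3 for miR-1293 and 3 for miR-3116, and 19 of 57 list calls were lost. The dim gene filter left 3 lists for miR-1293 and lost 8 calls. Cyclic loess lost 4, averages 3, only the 6 arrays 4, array weights 1 and leaving out 1 array 17 of 342. Against the other 9 mimics 12 of 57 were lost and 13 turned, and miR-3116 had 3 shifted lists. DNA replication turned with miR-4672 (0.159), miR-6859-3p (0.133), miR-34b-3p (0.136) and miR-127-5p (0.228), and mitosis with miR-4672 (0.15), miR-6859-3p (0.018), miR-34b-3p (0.184) and miR-6514-3p (0.006). Hypoxia turned with miR-4672 (-0.063), miR-34b-3p (-0.027), miR-6514-3p (-0.048), miR-1293 (-0.012) and miR-3116 (-0.009). There the other mimics had the larger mean change.

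Of the 694 gene changes named by rule, cyclic loess ended 12, median centring 15, trend and robust moderation 4, array weights 39 and averages 26, and the dim gene filter 0 of 659. Only the 6 arrays ended 370 of 630, and the other 9 mimics as reference ended 220 and turned 41 of 630. For 234 of 694, leaving out at least 1 array ended the call.

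With the replicate number as a block (no pairing was found), the gene counts were 1915, 1660, 2139, 1144, 908, 350, 1804, 790, 1749 and 743 in the same order, and 11 of 694 gene calls ended, AGO1 with miR-1293 among them (-0.25, adjusted p = 0.0596).

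For each mimic, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1885, 1650, 2154, 1145, 947, 361, 1806, 792, 1743 and 737 genes, and was the 1 split with as many, beside 5, 1, 1, 3, 2, 2, 2, 1, 1 and 2 for the highest other. Every other split of the 6 put mimic and control arrays on both sides, which shrinks any difference and widens the spread. Their low counts were thus set largely by the splits and give no measure of chance. For the mean of 10 mimics, 1 of 100 splits, the real one, gave as many genes in a fit of 3 arrays against 30 (39 genes, beside 22 for the highest other, which set control replicate 2 with miR-1293 replicates 2 and 3 apart). Chance is excluded there only for any 3 arrays drawn from the 33, as these splits break up the triplicates. With groups kept whole, 10 of 11 had a count at least that of the control, so it did not stand apart more than others. As counts of mimics include their own effects, an offset of the control stays open. Signal over background limits H4C12, FGF8 and PRB4, which were not detected on all arrays compared.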

Other observations

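All tests of this part were chosen after results had been seen.

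NT5E rose more with mimics under which cell cycle genes fell more. Across the 10 mimics, the NT5E change and the mitosis list mean had r = -0.835 (permutation p = 0.0019, adjusted p = 0.0214 over the 21 lists), rho -0.842 (permutation p = 0.00386, adjusted p = 0.0405) and r = -0.761 without the 2 farthest mimics. The DNA replication list gave r = -0.816 (adjusted p = 0.0214), rho -0.855 (adjusted p = 0.0405) and r = -0.801. The TGF-beta list gave r = 0.844 (adjusted p = 0.0214), rho 0.624 (adjusted p = 0.32) and r = 0.58, and the other 18 did not pass. NT5E following the fall of cell cycle genes may account for part of its spread, but the order of events was not tested. The mimics with the largest NT5E changes, miR-3126-5p, miR-134-3p, miR-6514-3p and miR-3116, also changed the most genes (2154, 1885, 1806 and 1743). With miR-224-3p, 1650 genes changed and NT5E rose by only 0.36. That mimic departs from the cell cycle relation as well. Its mitosis list mean was -0.507, while miR-6859-3p had -0.376 and a larger NT5E change, 0.41. No correlation of NT5E with the number of genes changed was computed, so the relation is not shown to be particular to cell cycle genes.

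Among 65 histone genes, 39 were lower with miR-3126-5p and with miR-3116, 36 with miR-134-3p, 31 with miR-6514-3p, 30 with miR-224-3p, 24 with miR-6859-3p, 16 with miR-4672, 12 with miR-34b-3p and 3 with miR-127-5p. A single one was higher with each of miR-134-3p, miR-3126-5p, miR-6514-3p and miR-1293. Among 994 gene ontology terms of 15 to 300 genes, tested with camera, phagosome maturation was higher with miR-6514-3p (21 genes, mean 0.232, adjusted p = 2.73e-08, and 0.00118 with an estimated correlation). That mimic had 15 terms higher and 28 lower, of which 10 and 16 held with an estimated correlation. With miR-127-5p 0 terms were higher and 3 lower, of which 0 held, and with miR-1293 0 were higher and 0 lower. Phagosome maturation was also higher with miR-4672 (adjusted p = 0.00818, and 0.0865) and miR-6859-3p (adjusted p = 0.0308, and 0.162). With miR-6514-3p, ATP hydrolysis coupled proton transport (adjusted p = 1.93e-05, and 0.0166) and transferrin transport (adjusted p = 0.000313, and 0.0155) were higher too. Whether these terms share their genes with phagosome maturation was not tested. Mitophagy (34 genes) was higher with miR-6514-3p (mean 0.135, adjusted p = 0.00178, and 0.0123) and miR-3116 (mean 0.111, adjusted p = 0.0208, and 0.0405). Lower terms numbered 55 with miR-3126-5p, 49 with miR-134-3p, 36 with miR-3116, 32 with miR-4672, 28 with miR-6859-3p, 27 with miR-224-3p and 22 with miR-34b-3p, of which 37, 28, 27, 5, 8, 18 and 10 held. DNA replication (141 genes) was lower with miR-3126-5p (adjusted p = 4.98e-18, and 2.27e-05), but was lost with an estimated correlation with miR-4672 (adjusted p = 0.00157, and 0.0865) and miR-127-5p (adjusted p = 0.00772, and 0.283), as was DNA strand elongation with miR-4672 (adjusted p = 0.00139, and 0.252), miR-6859-3p (adjusted p = 2.8e-05, and 0.162) and miR-127-5p (adjusted p = 1.75e-06, and 0.283). NT5E differed among the 10 mimics (limma F test, adjusted p = 0.00158), as did 6492 genes in all.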
